A study of Homo sapiens with 2 samples.

How the data were processed

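RNA from Seg-1 cells was measured on Affymetrix Human Genome U133 Plus 2.0 microarrays, on which a set of short oligonucleotide probes (a probe set) reports each transcript. Seg-1 was first taken for an esophageal adenocarcinoma line, and per the labels' protocols it is the lung line H460. One array carried RNA from cells transfected with a negative control siRNA that matches no known gene, and 1 array carried RNA from cells transfected with an siRNA against FGF-AS, the antisense transcript of the fibroblast growth factor 2 locus. Per the labels' protocols, cells were harvested 72 hours after transfection, siRNA was used at final concentrations between 25 and 200 nM, and total RNA was primed with oligo-dT carrying a T7 promoter and transcribed into biotin-labelled cRNA. The concentration behind each array is not given in the sources used here. Both groups hold 1 array, so no difference has a replicate check and no p-value is given.

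The deposited values are probe set intensities on a linear scale that the authors obtained from the scanned arrays, and the submitters' processing notes name GCOS and MAS5 with no version, role or scaling target. MAS5 summarises the probes of a set into 1 signal per array. The deposited intensities ran from 0 to 21359.6 on the control array and from 0.1 to 20791.3 on the FGF-AS siRNA array. Their medians were 25.6 and 23.1, and their means after removal of the lowest and the highest 2% of probe sets were 172.5 and 167.0, so the arrays had similar but not equal scales. How they were scaled against each other stays unknown. Detection calls and raw probe intensities were not used here, so a low intensity cannot be told from background, and a signal on an array carries no counting error. The number of arrays limits the precision.

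The table held 54675 probe sets, of which 62 were Affymetrix controls. Of the 54613 others, 41091 were annotated to 1 gene symbol, 1801 to several and 11721 were unnamed here. Probe sets with several symbols were given no gene name. Symbols were looked up by gene identifier in a RefSeq table (assembly GRCh38.p14), which covered 41037 of the single-symbol probe sets and changed none, and 54 kept the annotation's symbol. No genome coordinates were used.

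The log2 ratio was log2(FGF-AS siRNA signal + 6.1) minus log2(control signal + 6.1). The offset of 6.1 is the 25th percentile of all non-control signals, and it understates the change of dim genes. No further scaling was applied. Each gene was represented by its brightest single-symbol probe set, by the mean of both arrays. A gene counted as measured when that mean was at least 23.9, the median over probe sets, which left 12352 of 19775 genes. A stricter minimum of 145.2 (the 75th percentile) left 7719 genes. The size threshold was a 2-fold difference. The only available error was the disagreement between probe sets of one gene, given as the SD of the log2 ratio of a single probe set. It covers neither differences between cultures nor differences between hybridisations.

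The offset, the minimum, the 2-fold size, the stricter minimum as an alternative, 25 gene lists (20 of pathways, complexes and gene families, 5 of cell type markers) and the rule for named genes were fixed before the data were examined. For each list the median log2 ratio of its measured genes was set against the medians of 10000 random lists of the same size, drawn from measured genes in the same of 10 equal bins of mean signal. A list was said to stand apart at or under percentile 2.5 or at or over percentile 97.5, which chance alone gives for about 5% of lists of unrelated genes. Genes of a pathway vary together, so this percentile describes these 2 arrays and is not a test across cultures. Named genes were NUDT6, FGF2 and AGO2 with all probe sets, the 12 highest and 12 lowest measured genes, up to 4 leading members of each list that stood apart, the member furthest from 0 in every other list, and the 5 highest and 5 lowest genes among those whose several measured probe sets all passed 2-fold in one direction. Dim genes filled those extremes, so the 12 highest and 12 lowest at the stricter minimum were added after the values were seen, as was the split of the SD by signal. CDKN1A, GDF15, CCNE1, TOP2A, KIF23, UGDH, H2AX, DICER1, CASP9, CXCL8, NFKB2, CCN1 and CCN2 were chosen after their values were seen. The 5' over 3' signal ratios of human control genes are not reported here.

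The procedure was tested on simulated data in which up to 200 genes of this comparison were changed and single ratios varied with an SD of 0.35. Among 12339 genes run, 99.0% of genes changed by 2 on the log2 scale and 73.7% of those changed by 1.3 passed 2-fold, against 0.25% of unchanged genes. That SD is below the one measured over all genes, and with the measured SDs (0.34 for brighter and 0.58 for dimmer genes) 3.44% of unchanged genes passed 2-fold on average over 100 simulations. Of 200 unchanged lists of 25 genes, 6% stood apart, and 96.5% did after a shift of 0.3. These list shares come from the SD of 0.35 alone and were not run at the measured SDs. The share of 96.5% may therefore overstate what could be seen in smaller, dimmer or more variable lists. Alternatives to the offset, the signal minimum, the scaling between arrays (median centring, quantile normalization, loess with span 0.3), the choice of probe sets and the size threshold were tried. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.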

Results

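Gene expression in Seg-1 cells was compared between 1 culture transfected with FGF-AS siRNA and 1 transfected with negative control siRNA, both harvested at 72 hours. Signals of 54675 probe sets were available for each array. Across probe sets, log2 signals of the arrays correlated with Pearson's r of 0.92, and with r of 0.96 among probe sets at or above the signal minimum. Of the 12352 measured genes, 82.5% lay within 1.5-fold of each other on the arrays. The SD of a single probe set's log2 ratio, from the disagreement between probe sets of one gene, was 0.48 (1.40-fold) over 6155 genes. It was 0.34 among probe sets at or above the stricter minimum (3050 genes) and 0.58 among dimmer ones (2365 genes). These SDs measure disagreement within the 2 arrays only. With 1 array per group no difference below could be tested against variation between cultures.

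The target of the siRNA was examined first. NUDT6, the gene that encodes the antisense transcript FGF-AS together with a nudix hydrolase protein, was lower with FGF-AS siRNA on both of its probe sets. Its brighter probe set (230329_s_at) read 376.9 with control siRNA and 104.5 with FGF-AS siRNA, 27.7% of control and a log2 ratio of -1.79. The other (220183_s_at) read 267 and 77.8, or 29.1% of control, with a log2 ratio of -1.70. Both ratios were several times the probe set SD of 0.34. NUDT6 ranked 8th lowest of the 7719 brighter genes and 55th lowest of all 12352.

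FGF2, a heparin-binding growth factor whose gene overlaps NUDT6 on the opposite strand, was the sense partner of interest. Its probe set 204422_s_at read 676.2 with control siRNA and 911.8 with FGF-AS siRNA, 1.35-fold higher with a log2 ratio of 0.43. Its probe set 204421_s_at read 326.7 and 338.8, a log2 ratio of 0.05. The first ratio was slightly larger than the probe set SD of 0.34, at percentile 86.6 of measured genes, and the second was smaller than the SD. A difference in FGF2 mRNA was not resolved by these arrays. Labelled cRNA made from oligo-dT primers keeps the strand of the transcript, so the FGF2 and NUDT6 probe sets report different strands.

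AGO2, which encodes Argonaute-2, the slicing enzyme of RNA interference, read 1268.4 with control siRNA and 822.2 with FGF-AS siRNA on its single-gene probe set (225827_at). The log2 ratio of -0.62 (64.8% of control) was larger than the probe set SD of 0.34 and lay at percentile 8.34 of measured genes. Probe sets annotated to AGO2 together with a second gene did not all go the same way: 225569_at had a log2 ratio of -0.45, 213310_at of 0.27 and the dim 1561042_at of -0.78. The 28 measured genes of the RNA silencing machinery had a median log2 ratio of -0.01, at percentile 46.9 of random lists, with 14 genes above and 14 below 0. At the extremes of this list were AGO4, a further Argonaute gene, which was dim and 2.53-fold higher (38.6 to 107), and DICER1, the nuclease that cuts small RNA precursors, which was 2.07-fold lower (1347.5 to 647.9). All 3 measured probe sets of DICER1 were lower, with log2 ratios from -1.44 to -0.83.

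**Figure D1:**
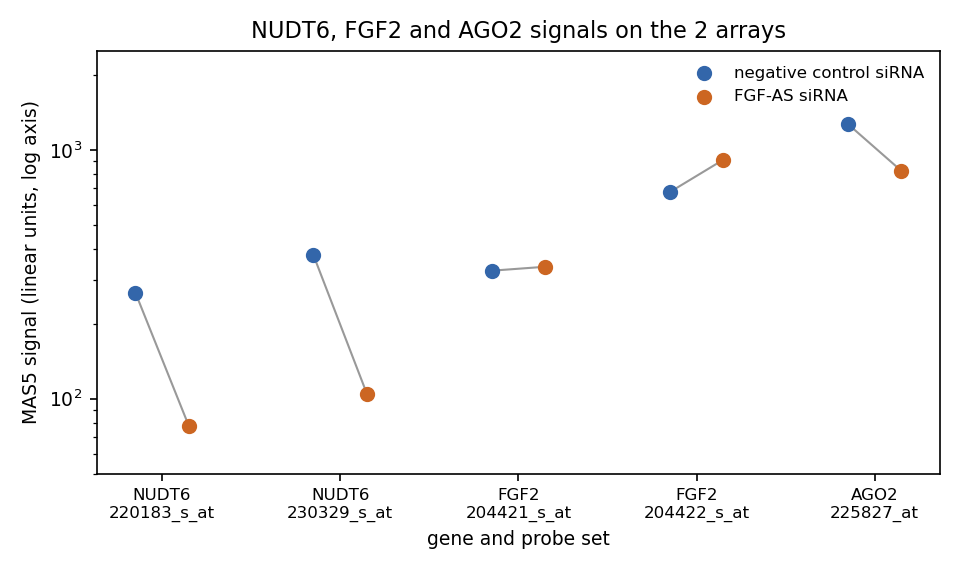
MAS5 signal (linear units on a log axis) of each single-gene probe set of NUDT6, FGF2 and AGO2 on the negative control siRNA array and the FGF-AS siRNA array; each point is 1 array and no error bar can be drawn. NUDT6 was lower on both probe sets (376.9 to 104.5 and 267 to 77.8), FGF2 was higher on one (676.2 to 911.8) and nearly level on the other (326.7 to 338.8), and AGO2 was lower (1268.4 to 822.2).

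Neither list of FGF pathway genes stood apart from random lists. The 11 measured FGF ligands and receptors, FGF2 included, had a median log2 ratio of -0.08 (percentile 35.5), with the dim binding protein gene FGFBP1 furthest from 0 at -0.75. The 29 FGF and ERK response and feedback genes had a median of 0.08 (percentile 86.4), with 18 above and 11 below 0. Of these, 6 were at least 1.5-fold higher and 1 was at least 1.5-fold lower. Over the alternatives the percentile of this list ran from 59.0 to 94.9. PLAUR, the urokinase receptor gene, was the member furthest from 0 at 1.02 (154.7 to 320.4), and its other 2 probe sets gave 1.35 and 1.44. The 13 measured genes of the FGF2 and NUDT6 neighbourhood on chromosome 4, both included, had a median of 0.06 (percentile 71.1), and NUDT6 was their only member past 2-fold. This list stood apart as higher at the stricter minimum (median 0.29). The 19 other nudix hydrolase genes had a median of -0.11 (percentile 16.3), with NUDT13 furthest from 0 at -0.81 on its brightest probe set (0.17 on the other) and no member past 2-fold.

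Genes of the cell cycle were higher with FGF-AS siRNA. Of 36 measured G2/M and mitosis genes, 34 had a log2 ratio above 0, and their median was 0.48 (1.40-fold; SD across genes 0.28), above all 10000 random lists. The leading members were KIF11, a spindle motor, at 2.21-fold (435.5 to 970), CDC20, an activator of the anaphase-promoting complex, at 1.91-fold (808.4 to 1549.1), CENPE, a kinetochore motor, at 1.80-fold (170 to 310.5), and KIF4A, a chromosome-bound motor, at 1.73-fold (611.5 to 1062.4). KIF11 was the only member past 2-fold, and 12 members passed 1.5-fold. The exceptions below 0 were TOP2A at -0.21 and KIF23 at -0.08, and KIF23 moved to 0.033 under median centring. Of 35 DNA replication and G1/S genes, 34 were above 0, with a median of 0.36 (1.28-fold; SD across genes 0.26), again above all random lists. CDT1, a replication licensing factor, was 1.89-fold higher, CCNE2, a G1/S cyclin, 1.81-fold, E2F1, a transcription factor of the G1/S transition, 1.80-fold, and FEN1, a flap endonuclease, 1.63-fold. Their other probe sets gave smaller log2 ratios, of 0.27 for CDT1, 0.31 for CCNE2, 0.58 for E2F1 and 0.49 for FEN1. None passed 2-fold, and CCNE1 was the only member below 0 at -0.40. In this list 8 members passed 1.5-fold. Single members of both lists thus differed by little, and it was their common direction that set the lists apart.

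Targets of the tumour suppressor p53 were lower with FGF-AS siRNA. Of 25 measured targets, 22 had a log2 ratio below 0, and the median was -0.56 (1.47-fold lower; SD across genes 0.44), below all 10000 random lists. The 4 targets past 2-fold were SESN2, a stress-induced regulator of growth signalling (733.5 to 247.7, log2 ratio -1.54, but -0.79 on its other probe set), TP53I3, an oxidoreductase gene (1332.2 to 584.6, -1.18), ZMAT3, an RNA-binding zinc finger gene (595.2 to 279.8, -1.07), and MDM2, the ubiquitin ligase of p53 (1649.7 to 816.7, -1.01). All 8 measured probe sets of MDM2 were lower, 7 of them with log2 ratios from -1.82 to -0.71, while the ratio of the other (84.2 to 1.4) depends on the offset. With FGF-AS siRNA this probe set and 2 further dim ones (17.1 and 20.6) read under the signal minimum. CDKN1A, the cyclin-dependent kinase inhibitor p21, read 2237.4 and 1236.4, a log2 ratio of -0.85. GDF15, a secreted stress cytokine, went against the list at 0.50 (3998.2 to 5643.3). Apoptosis regulators as a group did not stand apart (26 genes, median -0.04, percentile 35.5). Past 2-fold in that list were the initiator caspase genes CASP10 (-1.09) and CASP9 (-1.01, and -0.58 on its other probe set), both lower. CASP10 was dim (47.5 to 19) and read under the signal minimum with FGF-AS siRNA. Its ratio ran from -1.32 to -0.73 over the alternatives. The median of this list turned to 0.36 (percentile 99.6) at the stricter minimum without probe sets ending in _s_at or _x_at, an alternative chosen after seeing the data.

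Genes of cholesterol synthesis were higher, and NRF2 targets and histone genes lower, by smaller amounts. Of 18 cholesterol biosynthesis genes, 14 were above 0 with a median of 0.33 (SD across genes 0.39, percentile 99.98). Over the alternatives tried, the median of this list ran from 0.19 to 0.50. Its leading members were the dim TM7SF2 at 1.04, FDPS at 0.80 (1800.6 to 3148.7), HMGCS1 at 0.79 on its brightest probe set but -0.09 on the other, and STARD4 at 0.72. Of 23 targets of NRF2, the regulator of the oxidative stress response, 21 were below 0 with a median of -0.17 (SD across genes 0.32, percentile 0.18), and over the alternatives tried the percentile stayed at or under 2.36 while the median ran from -0.26 to -0.05. ABCC3, a transporter, read -1.25 on its brightest probe set and between -0.95 and 0.04 on 4 others, followed by OSGIN1 (-0.72), CYP4F11 (-0.37) and ABCC2 (-0.36), while UGDH stood at 0.52. Of 13 histone genes, 10 were below 0 with a median of -0.36 (SD across genes 0.45, percentile 0.46), led by H2AC6 (-1.07), H2BC6 (-0.71) and the dim H2AC8 (-0.60) and H2BC4 (-0.58), while H2AX stood at 0.72 (-0.24 to 0.42 on its 2 other probe sets). The histone call ended when probe sets ending in _s_at or _x_at were left out (median -0.30, percentile 5.5), when this was combined with the stricter minimum (-0.12), and with the mean over probe sets (-0.28). Histone gene copies share sequence, so signals of single histone genes are uncertain.

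**Figure D2:**
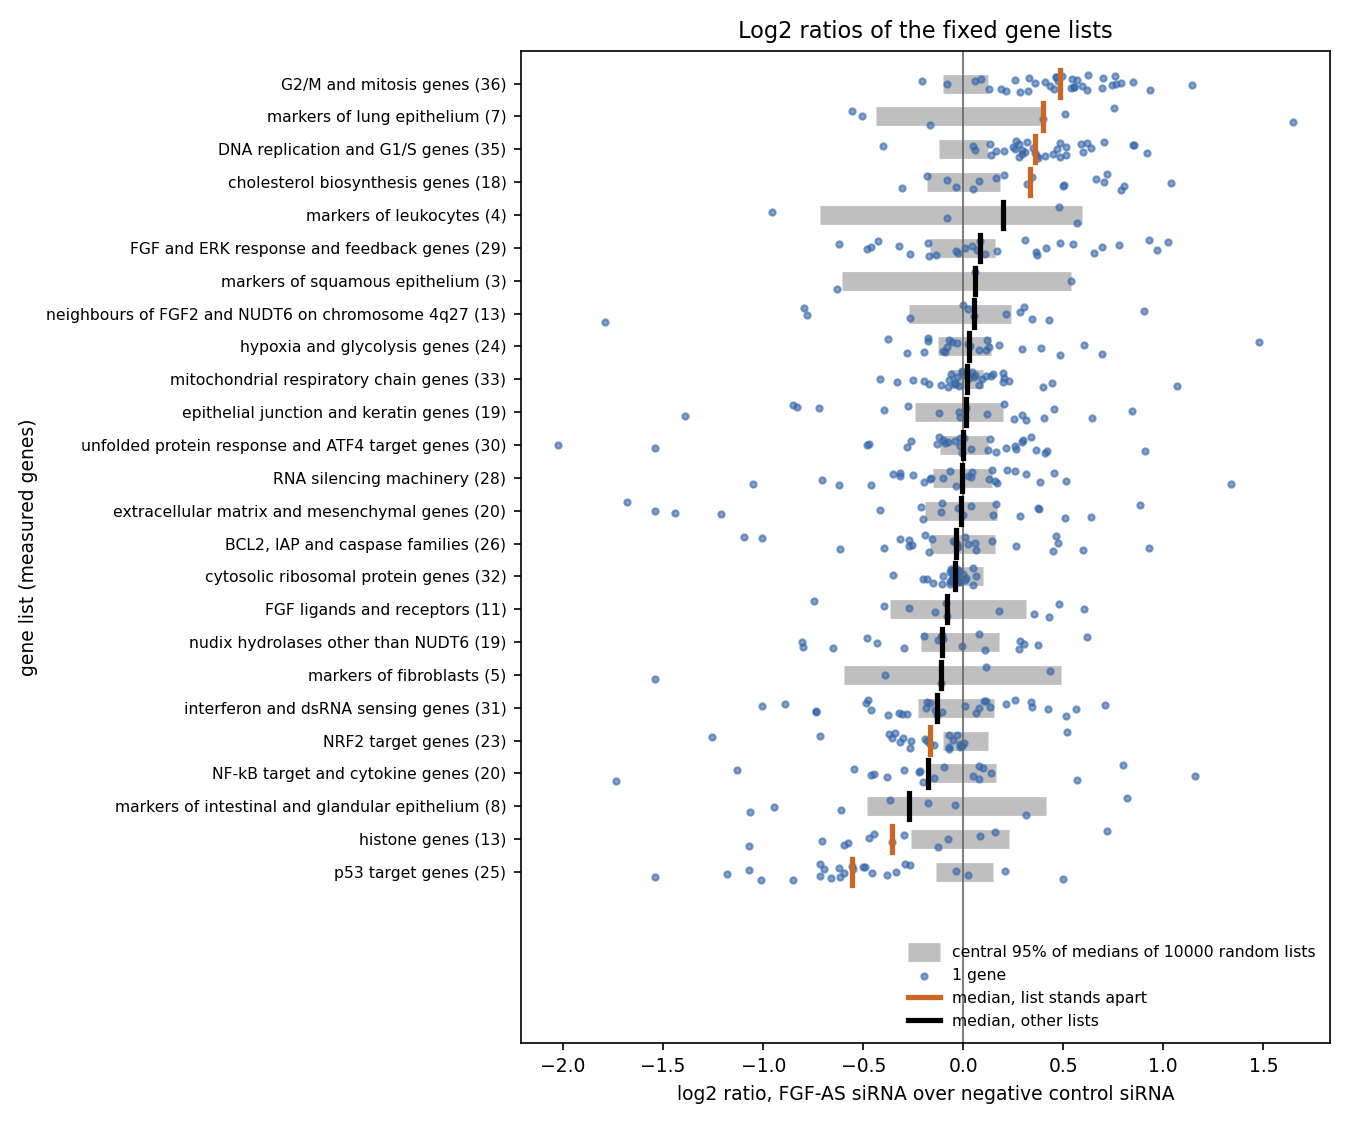
Log2 ratio (FGF-AS siRNA over negative control siRNA) of each measured gene in the 25 lists; points are genes, vertical bars are list medians (orange where the list stands apart) and grey bands span the central 95% of medians of 10000 random lists matched on signal. The G2/M list (median 0.48) and the replication list (0.36) lie above their bands and the p53 target list (-0.56) below its band.

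In all, 7 of the 25 lists stood apart. Besides the 6 above this was the list of lung epithelium markers (7 measured genes, median 0.40, percentile 97.8), in which 4 genes were above 0. SFTPC (14.7 to 59.1), CLDN18 (26.1 to 48.2) and NAPSA (31.9 to 44) were dim, and LPCAT1 read 545.6 and 778.5. The 3 lower markers were HOPX (766.8 to 519.4, log2 ratio -0.56), FOXA2 (-0.51) and SFTPB (-0.17). This call ended with a larger offset (median 0.28, percentile 96.3) and without probe sets ending in _s_at or _x_at (0.51, percentile 95.5). Lists for other cell types had few measured members and did not stand apart: squamous epithelium (3 genes, median 0.06, SPRR1A -0.63), intestinal and glandular epithelium (8 genes, -0.27, TFF1 -1.06), fibroblasts (5 genes, -0.11, COL3A1 -1.54) and leukocytes (4 genes, 0.20, CD14 -0.96). TFF1 (39.5 to 15.7) and CD14 (38.3 to 16.8) were dim and read under the signal minimum with FGF-AS siRNA.

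The interferon-stimulated and double-stranded RNA sensing genes, which siRNA can induce, were not higher with FGF-AS siRNA than with control siRNA. Their median was -0.13 over 31 genes (percentile 14.0), 17 were below 0, and TLR3 was the only member past 2-fold at -1.01 on its brightest probe set (-0.27 on the other). Both arrays came from siRNA-transfected cells and none from untransfected cells, so an induction common to both would not show. NF-kB targets and cytokine genes had a median of -0.17 (20 genes, percentile 3.35) with members past 2-fold both ways: IL1A at -1.74 on its brightest probe set but -0.19 on the other, NFKB2 at -1.13 (-0.73 on the other), and CXCL8, which encodes the chemokine interleukin 8, at 1.16 (3306.6 to 7379.4; 0.85 on the other probe set). The extracellular matrix and mesenchymal list had a median of -0.01 (20 genes, percentile 50.7), although 4 of its members were at least 2-fold lower. These were ACTA2, smooth muscle actin (1141.3 to 351.3), COL3A1, a fibrillar collagen (316.4 to 104.6), and the matricellular protein genes CCN2 (1452.2 to 530.2) and CCN1 (1224.2 to 524.8). At the stricter minimum, the interferon (median -0.33), NF-kB (-0.21) and extracellular matrix (-0.20) lists stood apart as lower, and the NF-kB list also did under quantile normalization (-0.12) and with the mean over probe sets (-0.26), so for these lists the outcome depends on the settings. The unfolded protein response and ATF4 list had a median of -0.00 (30 genes, percentile 49.1), with DNAJC3 (-2.03) and SESN2 (-1.54) past 2-fold. The hypoxia and glycolysis list stood at 0.03 (24 genes, percentile 66.1, ENO2 1.48) and the epithelial junction and keratin list at 0.01 (19 genes, percentile 62.0, TJP3 -1.39). The mitochondrial respiratory chain list stood at 0.02 (33 genes, percentile 56.0, NDUFA5 1.07). Cytosolic ribosomal protein genes varied least of the 25 lists, with a median of -0.04 and an SD across genes of 0.08 (32 genes, percentile 11.4, RPLP2 -0.35), and this median changed sign between scalings (-0.07 to 0.07 over the alternatives). RPLP2 was dim (45.3 to 34.2). The other members read from 9655.2 (RPL14, FGF-AS siRNA) to 21359.6 (RPS23, control siRNA), at the top of the signal range. Their small spread says little about dimmer genes.

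Over all measured genes, 253 were at least 2-fold higher and 336 at least 2-fold lower with FGF-AS siRNA, so that 43.0% of these genes were higher. This split depends on the scaling: the share of higher genes was 61.1% under median centring, 63.4% under quantile normalization and 57.7% under loess. Median centring moved the median log2 ratio of measured genes from -0.02 to 0.10. Most of these genes were dim, and at the stricter minimum 76 were higher and 86 lower. If no gene differed and single ratios varied by the SD between probe sets, simulation put 396.9 of the 4633 dimmer genes past 2-fold, against 427 observed, and 27.6 of the 7719 brighter genes, against 162 observed. The draws were normal, and that SD comes from these same 2 arrays and can also hold differences between transcript ends. Over all genes it was 0.48, the same as the SD of the gene ratios. Near equality of simulated and observed counts among dim genes therefore cannot tell noise from change. Among dim genes past 2-fold with a second measured probe set, 22% had it past 2-fold in the same direction, against 6.5% on average for dim genes. Among bright genes the shares were 26.9% and 3.64%.

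Among the genes at the stricter minimum, the highest log2 ratios were those of CHPF, a chondroitin synthesis gene (73.3 to 374.3, 4.79-fold), HIPK3, a nuclear kinase gene (125.7 to 613.2, 4.70-fold), TLN1, which encodes the integrin adaptor talin (89.4 to 381.1, 4.05-fold), HKDC1, a hexokinase-like gene (3.39-fold), and EMP2, an epithelial membrane protein gene (3.20-fold). SPOPL, RTN1, RELL1, SOCS4, HS6ST1, IL6ST and STEAP3 completed the 12 highest, at log2 ratios between 1.60 and 1.48. The 2 other probe sets of HKDC1 gave 1.36 and 0.41, the second of HIPK3 gave 0.44, that of SOCS4 gave -0.20 and that of HS6ST1 gave 0.12, and the 4 others of IL6ST, the shared receptor subunit of interleukin 6 cytokines, ran from -0.88 to 0.45. The lowest log2 ratios were those of HPD, a tyrosine breakdown enzyme (738.8 to 65.9, 10.3-fold), CBX5, heterochromatin protein 1 alpha (2168 to 419, 5.11-fold), GLP2R, a hormone receptor gene (4.39-fold), CES1, a carboxylesterase gene (4.33-fold), DNAJC3, an endoplasmic reticulum co-chaperone gene (4.07-fold), CBX6, a Polycomb gene (3.86-fold), and FOLR1, folate receptor alpha (2335.8 to 620.8, 3.74-fold). NUDT6, COXFA4L3, ACTA2, RASEF and TXNIP completed the 12 lowest, at log2 ratios between -1.79 and -1.66. The other 5 probe sets of CBX5 ran from -3.48 to 0.32, the other 3 of DNAJC3 from -2.05 to -0.07, the second of CBX6 gave -0.33 and that of RASEF -0.61. HPD, GLP2R, CES1, FOLR1, COXFA4L3 and ACTA2 had no other measured probe set, and neither had CHPF, TLN1 and RELL1 among the highest.

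Over all signal levels, the highest ratios came mostly from genes near the lower end of the signal range. Besides CHPF and HIPK3 the 12 highest were CTXN3, TNNT1, FZD4, DNAH1, RNF122, LINC01620, IGFBP4, MIRLET7D, PPP1R14B-AS1 and PRR12, with log2 ratios from 2.24 to 2.69. CTXN3 read 2 on the control array and 46.3 on the FGF-AS siRNA array, and IGFBP4, an insulin-like growth factor binding protein gene, 20.9 and 131.5. Besides HPD the 12 lowest were ADAM33, SYNC, ADAMTS14, CCDC13, METTL27, C22orf23, MED18, NRAP, GARIN5A, KCNIP2-AS1 and MAMDC4, with log2 ratios from -3.08 to -2.40. The second probe set of MED18 gave 0.37, the 2 others of CCDC13 gave -0.96 and -0.17, and the 2 others of DNAH1 gave -0.52 and -0.01. Signals this low depend on the offset, and their order carries little information.

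Agreement between probe sets was rarer. Of 6155 genes with at least 2 measured probe sets, 10 had all of them at least 2-fold higher and 23 had all of them at least 2-fold lower. The 5 highest by mean log2 ratio were EMP2 (2.01 over 3 probe sets), DISP3 (1.87), TMEM139 (1.85), ALCAM, a cell adhesion molecule gene (1.43), and HEY1, a Notch-responsive repressor gene (1.40). The 5 lowest were LOC100190986 (-2.27), INPP5D, an inositol phosphatase gene (-1.96), CARNMT1 (-1.84), NINJ2-AS1 (-1.77) and NUDT6 (-1.75). TXNIP, a thioredoxin-binding protein gene, followed with -1.68 over 3 probe sets. Several of these genes were dim, and the ranks of DISP3, TMEM139, LOC100190986, INPP5D and NINJ2-AS1 rest on readings under the signal minimum on one array (from 3.5 to 13.7), where the ratio depends on the offset.

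Spike-in and ribosomal RNA probe sets differed between the arrays. Hybridisation spike-ins, bacterial and phage RNA labelled beforehand, had a median log2 ratio of 0.01 over 18 probe sets (range -0.16 to 0.17). Poly-A spike-ins, which pass through labelling with the sample, had a median of -0.43 over 24 probe sets, and in 7 of 8 pairs the 5' probe set was lower relative to the 3' one. These are 2 pairs for each of 4 spike-in RNAs, and the pairs of the Lys RNA disagreed (log2 difference 0.16 and -0.64). The 5 ribosomal RNA probe sets at or above the signal minimum, by the mean of both arrays, were 4.24-fold to 9.33-fold higher on the FGF-AS siRNA array. These differences separate the same 2 arrays as the siRNA does, and so accompany every gene group described above.

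**Figure D3:**
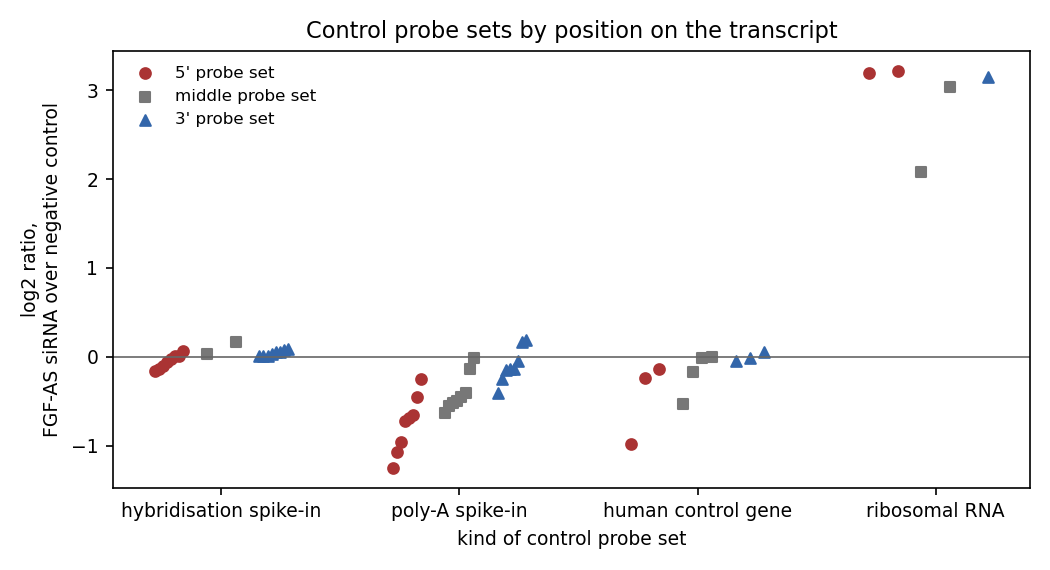
Log2 ratio (FGF-AS siRNA over negative control siRNA) of control probe sets at or above the signal minimum, by kind and by position on the transcript; each point is 1 probe set. Hybridisation spike-ins lie between -0.16 and 0.17, 5' probe sets of poly-A spike-ins reach -1.25, and ribosomal RNA probe sets lie between 2.08 and 3.22.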

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

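The tests of spike-ins, of the signal trend, of single cultures and of genes with several probe sets alone were chosen after the results were seen, and the tests on the highest probe set of every gene were set out before their outcome was known. Ribosomal RNA, which lies outside the gene comparisons, gave far more signal with FGF-AS siRNA than with control siRNA. The 18S ribosomal RNA probe sets were 8.87-fold higher at the 3' end, 9.14-fold at the 5' end and 8.23-fold in the middle (after the offset, and at the 5' end against a control signal of 11.4, under the signal minimum), and the 28S ones were 9.33-fold higher at the 5' end and 4.24-fold in the middle. The 3' probe set of 28S was under the signal minimum on both arrays (7.7 with control siRNA, 5.9 with FGF-AS siRNA).

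The ribosomal RNA signal went together with a loss of 5' signal in poly-A spike-ins. Hybridisation spike-ins had a median 5' minus 3' log2 ratio of -0.10, with all 8 pairs below 0 (-0.215 to -0.003), against -0.76 for poly-A spike-ins, of which 7 of 8 pairs lay below 0. The size of the difference, not its sign, sets both kinds apart, and it argues against hybridisation, washing or scanning as the whole cause. The 8 poly-A pairs come from 4 RNAs, of which 3 had both pairs below 0 and Lys had 0.16 and -0.64, so a difference in reverse transcription or labelling of the RNA stays open. Whether more ribosomal RNA entered the reaction or more of it was primed stays open, and no biological explanation was tested.

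The cell cycle lists were higher and the p53 target list lower. A trend with signal level does not account for the cell cycle shift, since the G2/M median was 0.53 after loess, against 0.48 before. Weaker labelling of 5' ends could lower single probe sets. The median of the highest log2 ratio per gene stood at percentile 0 of random lists for p53 targets and at percentile 100 for the combined cell cycle lists, but only 12 of 25 and 42 of 71 of these genes have several measured probe sets, and for the others this repeats the shift itself and decides nothing. Among genes with several probe sets alone, the percentile was 0 for 12 p53 targets (median -0.62) and 100 for 42 cell cycle genes (median 0.54). A gene's highest ratio cannot lie below the ratio that put the cell cycle lists apart, so the percentile of 100 decides nothing. For the p53 targets the highest ratio could have matched that of other genes, so their percentile argues against 5' labelling as the whole cause. That holds if these genes have a probe set near the 3' end, and probe set positions were not examined. Of the p53 targets 10 had all probe sets below 0 and 2 had all above, and of the cell cycle genes 27 had all above, 2 had all below and the others went both ways. Loss of 5' signal lowers a probe set, while the cell cycle medians were above 0 (0.48 and 0.36). No common lift of that size was seen. The median log2 ratio was -0.02 over measured genes and 0.01 over hybridisation spike-ins. On these 2 arrays, the values argue against weaker labelling of 5' ends as the whole cause of the higher cell cycle genes. For p53 targets with 1 probe set, weaker labelling of 5' ends stays open as a cause. With 1 array per group, the growth state of each culture and the effect of the siRNA, on its target or off it, cannot be told apart. That these opposite shifts follow from lower FGF-AS is an untested hypothesis.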

How the results depend on the processing

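The alternative that combined the 75th percentile minimum with removal of _s_at and _x_at probe sets was chosen after seeing the data. NUDT6 stayed between -1.85 and -1.64, FGF2 between 0.24 and 0.54 and AGO2 between -0.63 and -0.51 in every alternative that could measure them, and removal of _s_at and _x_at probe sets left no probe set for NUDT6 or FGF2. AGO2 was read by the same single-gene probe set throughout, so its narrow range says nothing about other probe sets. Those shared with a second gene ran from -0.78 to 0.27 under the main setting. The G2/M, replication, p53, cholesterol and NRF2 lists stood apart in the same direction under all alternatives. Genes at least 2-fold higher and lower numbered 129 and 165 with the offset at the median signal, 1074 and 1270 with no filter, 76 and 86 at the 75th percentile minimum, and 59 and 63 under the combined alternative. They numbered 983 and 1176 at 1.5-fold, 60 and 84 at 3-fold, and 326 and 459 with no offset. The higher genes outnumbered the lower ones under quantile normalization (371 and 214), median centring (363 and 231) and loess (332 and 243). Without a filter the added genes were those under the minimum signal. The histone list no longer stood apart with the mean over probe sets (-0.28), without _s_at and _x_at probe sets (-0.30) and under the combined alternative (-0.12), nor the lung marker list with the larger offset (0.28) or without _s_at and _x_at probe sets (0.51). At the 75th percentile minimum the lists of FGF2 neighbours (0.29), interferon genes (-0.33), NF-kB genes (-0.21) and extracellular matrix genes (-0.20) newly stood apart. The NF-kB list also did under quantile normalization (-0.12) and the mean over probe sets (-0.26), and under the combined alternative the interferon (-0.42) and extracellular matrix (-0.24) lists did. The apoptosis list turned to 0.36 and stood apart under the combined alternative. The cause was not tested. Among named genes, MED18 turned to 0.37 and ABCC3 to 0.040 without _s_at and _x_at probe sets and KIF23 to 0.033 under median centring, 65 values moved by more than the probe set SD and 871 did not. Most alternatives read the same probe set of a gene on the same 2 arrays. The 871 values therefore say little about other probe sets and nothing about other cultures. No paired analysis was possible because each group holds 1 array, and for the same reason neither array could be left out. Signal over background limits the dim genes, whose probe sets disagreed with an SD of 0.58.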

Other observations

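The 5 gene lists in this part were chosen after the data had been seen, and CCN1, CCN2, TXNIP and ERBB3, already seen among the extremes, were left out of them, while the tests of a second probe set were set out before their outcome was known. Targets of YAP and TEAD, the transcriptional arm of the Hippo pathway, had a median log2 ratio of -0.21 over 20 measured genes, at percentile 1.6 of random lists. Of these, 12 were below 0, but none was 2-fold lower. Lower genes included AJUBA (1460 to 834.5), PTPN14 (490.5 to 305.9) and IGFBP3 (3728 to 2449), while TGFB2 (143 to 311.3, past 2-fold) and TEAD1 (659.7 to 1251.8) were higher. FOXO targets had a median of -0.19 over 19 genes, at percentile 3.75, with KLHL24 (129 to 53), YPEL3 (40.3 to 9.8) and MXI1 (1285.6 to 753) lower and IRS2 (1391.4 to 2244) higher, and 3 of these genes are also in the p53 list. Nucleolar ribosome biogenesis genes had a median of 0.15 over 19 genes, at percentile 97.2, lysosomal genes 0.02 (22 genes, percentile 58.4) and proteasome genes -0.04 (27 genes, percentile 16.2). Of the 5 lists, those of FOXO targets, nucleolar, lysosomal and proteasome genes did not stand apart. None of the 5 was run under the processing alternatives. A lower YAP and TEAD output with FGF-AS siRNA may be worth testing in replicated cultures. It is a hypothesis from 1 of 5 lists, and the design leaves culture density, to which the pathway is known to respond, untested.

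Genes past 2-fold were only partly supported by a second probe set. Among dim genes past 2-fold with a second measured probe set, 22% (22 of 100) had it past 2-fold in the same direction, and among bright genes 26.9% (28 of 104) did. The second probe set had the same sign in 74% (74 of 100) and 77.9% (81 of 104). Among all genes of these signal levels, a second probe set passed 2-fold in a given direction in 6.5% and 3.64% on average. Both shares lie between the bounds set beforehand, 10% for noise alone and 50% for agreement, so the part of noise among the genes past 2-fold stays open. Probe sets of one gene can also report different transcript ends.

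CBX5 had probe sets that differed widely. Of its 6 measured probe sets, 3 had log2 ratios of -2.35, -3.21 and -3.48, and the others had -0.17, 0.05 and 0.32. The 4 probe sets of DNAJC3 had -2.03, -2.05, -1.06 and -0.07. The place of these probe sets on the transcripts was not examined here. Measured probe sets with no single gene symbol were at least 2-fold lower in 240 cases and at least 2-fold higher in 78, of 4085.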
